A study of Oryza sativa Japonica Group with 9 samples.

How the data were processed

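Total RNA from rice vegetative stem, taken at 30 days after imbibition from the lowest 1 cm above ground, was measured on 9 one-colour oligonucleotide arrays, with 3 arrays for each of 3 groups. Koshihikari, a japonica cultivar, was the control. SLqEPD1 and SLqEPD2 are chromosome segment substitution lines, each carrying the allele of the indica cultivar Habataki at the locus it is named after in an otherwise Koshihikari background. Groups and replicate numbers were taken from the labels. Per the labels' protocols, plants grew in a greenhouse and Cy3-labelled cRNA was made after a spike-in mix was added; the series design calls the 3 samples of a group biological replicates.

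Per the file headers, the scans were processed with Agilent Feature Extraction 10.5.1.1, and the processed intensity of each spot is background-subtracted and detrended within its array, with no scaling between arrays. The raw mean intensity and the local background median come from the same scanner output, per the file headers. The deposited value table is on a log2 scale; its processing is not given in the sources used here, so each of its columns was set against the scanner values of that array. For Koshihikari and SLqEPD2 it follows log2 of the processed intensity closely (across-spot r of at least 0.99997), but its difference from it was not constant within an array: the median difference was lower for dim than for bright spots on each of these arrays, for example 0.02 for bright and -0.11 for dim spots on Koshihikari replicate 3. The 3 SLqEPD1 columns of the deposited log2 table behave as if an offset of 10.5 to 14.8 intensity units had been added first: their smallest values are 3.92 to 3.96, against 1.90 to 2.17 for the other columns. The column medians of that table are 9.89 to 10.05. What the offset is and why it was applied to 1 group remain unknown, and the table served only as an alternative.

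Each array holds 43734 non-control spots. The files pair each spot with a probe ID and a 60-base sequence and with no gene, and 0 of the probes have a chromosome position in the files. The gene table used here lists 39387 rice genes without sequences, and 0 of the 92 gene identifiers in the 23 gene lists fixed before the data were examined matched an entry of the files. The list tests and the test per chromosome were therefore not run, and results are given per probe. In place of windows of the genome, the position test used windows of 500 consecutive probe numbers; how the numbering of the probes was assigned is not given in the sources used here.

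Spots that carry 1 sequence under several IDs were averaged as 1 probe, named by its lowest number, which left 38007 probes. Values are log2 of the processed intensity minus the array's 75th percentile over non-control spots. Outlier spots, 15 to 35 per array, were left out, and 0 spots were saturated. A probe was tested if it was well above background on all 3 arrays of at least 1 group; 12 such probes without a value in some group after outlier removal were dropped, and 32532 probes remained. Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes over all 9 arrays with a mean per group, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. Standard errors of differences come from that fit. Windows were tested with Fisher's exact test, one-sided for enrichment, with adjustment over the 88 windows. In addition, blocks of 20 neighbouring probes were shuffled 10000 times and the highest count in any window was recorded, which keeps runs of neighbouring probes together.

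A probe well above background on every array of 1 group and on no array of the other has only an approximate lower bound on its fold change. The bound sets the mean of the bright group against a mean over the dim arrays. Each dim array enters with the higher of the probe's own value and the lowest value among probes well above background. That lowest value is not a detection limit for every probe. A probe can go undetected at a higher value, so the bounds may be too large. The rule for named genes fixed in advance needed gene identifiers. It was replaced by the 2 higher and the 2 lower probes with the largest change per comparison, among probes past the threshold, well above background on every array of both groups, and with no overlap between the arrays of the 2 groups.

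The pipeline was tested on simulated data for SLqEPD1 against SLqEPD2, with 32532 probes run. It recovered 17.9% of probes shifted by 0.5 on the log2 scale, 77.6% of those shifted by 1 and 89.4% of those shifted by 2. Of its 133 calls, 10 were false, and the unchanged comparison of SLqEPD2 with Koshihikari gave 0 calls. The spread between spots of 1 sequence on 1 array was 0.0917 (SD, log2). The median spread of a probe within groups was 0.135, as the moderated SD from eBayes. Both values cover probes well above background on every array. The number of arrays limits the precision.

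The headers place the arrays on 3 slides, called A, B and C here. Slide A holds the 3 Koshihikari arrays and no other. Slide B holds SLqEPD2 replicates 1 and 2. Slide C holds SLqEPD2 replicate 3 and the 3 SLqEPD1 arrays. For the comparisons with Koshihikari the slide could enter only as a random block. That fit cannot remove an effect of slide A, so it does not test the slide against the cultivar. For SLqEPD1 against SLqEPD2 it was also fitted as a fixed block, and the comparison was repeated within slide C. In both of these the value for SLqEPD2 rests on its replicate 3 alone. Other alternatives were quantile normalization, the array median in place of the 75th percentile, and normexp background correction with offset 50 followed by quantile normalization, called normexp below. Further ones were the deposited value table, other detection filters, every probe ID on its own and the replicate number as a block. The rest were only the arrays of the 2 groups compared, a trended robust variance, array weights, stricter thresholds, other window widths and leaving out each array in turn. Counts of probes at which 1 line stood apart from both other groups, the comparison within slide C and the merging of overlapping neighbouring probes were added after seeing the data.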

Results

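Transcript levels in the stem base of young rice plants were compared between the cultivar Koshihikari and the substitution lines SLqEPD1 and SLqEPD2, with 3 arrays per group. The 75th percentile of the processed signal lay between 4810 and 7076 per array, and 83.4% to 87.0% of the probes were well above background. Over the 30695 probes well above background on every array, correlations between arrays of 1 group were 0.99 to 0.995. Correlations between the 2 lines were 0.984 to 0.991, and those between Koshihikari and a line were 0.955 to 0.968. The first principal component, with 62.2% of the variance, separated the Koshihikari arrays from those of both lines. The second, with 15.1%, separated the lines, and the SLqEPD2 array on slide C lay with the SLqEPD2 arrays on slide B. The 7 spike-in transcripts detected on every array averaged 0.49 ± 0.15 above the 75th percentile (log2, SD, n = 3) in Koshihikari, 0.52 ± 0.22 in SLqEPD1 and 0.67 ± 0.29 in SLqEPD2.

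**Figure D1:**
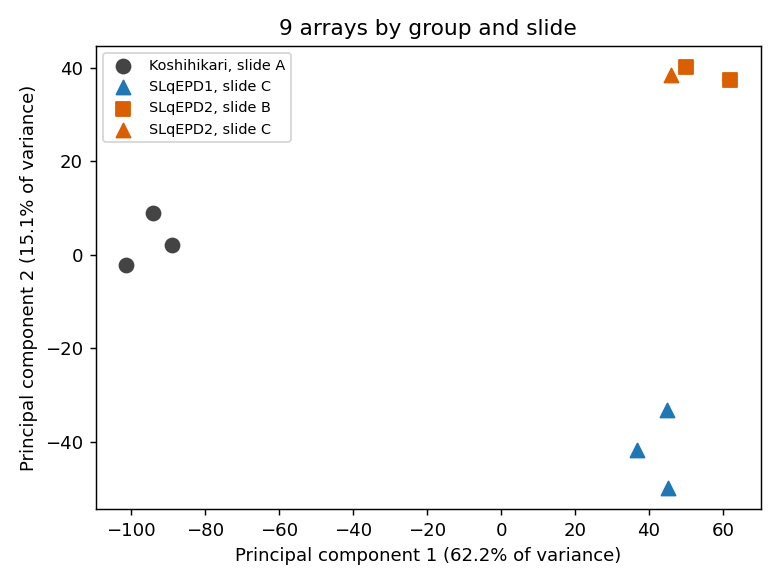
The 9 arrays on the first 2 principal components of the log2 signals of the tested probes, which carry 62.2% and 15.1% of the variance. Colours give the group and marker shapes the slide; the 3 groups lie apart on the plane, and the SLqEPD2 array on slide C lies with its own line.

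The first comparison asked which transcripts differ in the stem when the Habataki allele of qEPD1 is carried in the Koshihikari background. At 14102 of 32532 probes (43.3%) SLqEPD1 differed from Koshihikari, with 7634 higher and 6468 lower in the line. Changes of at least 2-fold were fewer, with 1808 probes higher and 1519 lower, and the median change over all tested probes was 0.02 on the log2 scale. The largest increase with a signal on both sides was at NIAS05940, which carries the sequence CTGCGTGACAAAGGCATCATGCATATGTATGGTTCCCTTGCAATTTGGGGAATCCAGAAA. Its level was -7.32 ± 0.35 (SD, n = 3) in Koshihikari and -0.16 ± 0.04 in SLqEPD1, a log2 difference of 7.16 ± 0.15 (SE) with an adjusted p of 1.64e-07 by limma. NIAS18902, with the sequence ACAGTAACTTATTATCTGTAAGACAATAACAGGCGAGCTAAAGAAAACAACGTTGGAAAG, was higher by 7.08 ± 0.16 (limma, adjusted p = 1.64e-07). The largest decrease measured on both sides was at NIAS32501, with the sequence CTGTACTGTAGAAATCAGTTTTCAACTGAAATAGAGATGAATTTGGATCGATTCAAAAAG. It went from 2.50 ± 0.13 in Koshihikari to -7.40 ± 0.64 in SLqEPD1, a log2 difference of -9.90 ± 0.29 (limma, adjusted p = 4.79e-07). NIAS38844, with the sequence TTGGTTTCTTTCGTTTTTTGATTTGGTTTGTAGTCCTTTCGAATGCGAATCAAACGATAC, differed by -9.57 ± 0.23 (limma, adjusted p = 2.3e-07). The size of these changes depends on the background correction of the dim side. With normexp followed by quantile normalization they were 5.56 at NIAS05940, 5.43 at NIAS18902, -8.16 at NIAS32501 and -7.64 at NIAS38844. Quantile normalization alone gave 7.12, 7.03, -9.84 and -9.54. At 321 of the called probes the signal was well above background on all SLqEPD1 arrays and on no Koshihikari array. The bound reached 78.2-fold and was at least 2-fold at 255 of them. At 79 the reverse held, with a bound of at least 2-fold at all 79 and of up to 2530-fold. On the SLqEPD1 arrays 85.6% to 87.0% of the probes were well above background, against 83.4% to 84.6% on the Koshihikari arrays. The arrays of the groups did not overlap at 55.4% of the tested probes, where chance gives 10%. Koshihikari lies on a slide of its own, so slide and cultivar cannot be told apart in this comparison. The balance of directions depended on the processing: 54.1% of the calls were higher in SLqEPD1 here, 65.6% with the deposited values, 47.8% with median scaling (6363 higher and 6958 lower), and without a detection filter 7556 were higher and 7949 lower.

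The second comparison put the same question for the Habataki allele of qEPD2. SLqEPD2 differed from Koshihikari at 15488 probes (47.6%), of which 8652 were higher and 6836 lower in the line. At least 2-fold changes numbered 2037 higher and 1791 lower, with a median over all probes of 0.04. The probes NIAS18902 and NIAS05940 again had the largest increases among probes measured on both sides, of 7.62 ± 0.16 and 7.08 ± 0.15 on the log2 scale (limma, adjusted p = 6.37e-08 and 7.88e-08). The largest decrease measured on both sides was at NIAS21937, with the sequence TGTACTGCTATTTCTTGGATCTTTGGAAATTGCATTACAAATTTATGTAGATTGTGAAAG. Its level was 3.57 ± 0.24 (SD, n = 3) in Koshihikari and -5.77 ± 0.14 in SLqEPD2, a log2 difference of -9.33 ± 0.18 (SE, limma, adjusted p = 4.76e-08). NIAS25732, with the sequence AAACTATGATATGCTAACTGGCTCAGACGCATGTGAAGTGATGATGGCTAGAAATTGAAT, differed by -8.77 ± 0.16 (limma, adjusted p = 3.58e-08). In SLqEPD1 the differences from Koshihikari were -9.08 ± 0.18 at NIAS21937 and -8.76 ± 0.16 at NIAS25732. With normexp the SLqEPD2 changes were 5.96 at NIAS18902, 5.48 at NIAS05940, -8.41 at NIAS21937 and -8.40 at NIAS25732. Signal was well above background on all arrays of SLqEPD2 and on none of Koshihikari at 254 called probes. The bound reached 303-fold and was at least 2-fold at 222 of them. The reverse held at 167, with a bound of up to 1592-fold and of at least 2-fold at 159. Groups did not overlap at 56.9% of the probes, against 10% by chance, and the slide limit given for SLqEPD1 holds here too.

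Most of these differences were shared by the lines. Both differed from Koshihikari in the same direction at 11697 probes, 6474 of them higher and 5223 lower in both. These are 82.9% of the SLqEPD1 calls and 75.5% of the SLqEPD2 calls. Independent lists of these sizes would share 2030 higher and 1359 lower probes. Simulated unchanged groups with shared controls shared 0 calls. Without any change few or no probes pass the threshold, so that 0 was nearly fixed in advance. It gives no expectation for lists of these sizes, and the simulation held no slide effect. At 2572 probes the change was at least 2-fold in both lines. Across probes, which are not independent replicates, the log2 changes of the lines correlated with r = 0.85, against 0.50 for simulated unchanged groups. Their covariance was 0.573 against a simulated 0.0209, a difference of 0.552. The 3 Koshihikari arrays cannot be split into groups of at least 2, and part of the excess over independent lists may come from the shared controls. At 11416 of the shared probes SLqEPD1 and SLqEPD2 did not differ past the threshold, and at 112 probes the lines differed from Koshihikari in opposite directions.

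**Figure D2:**
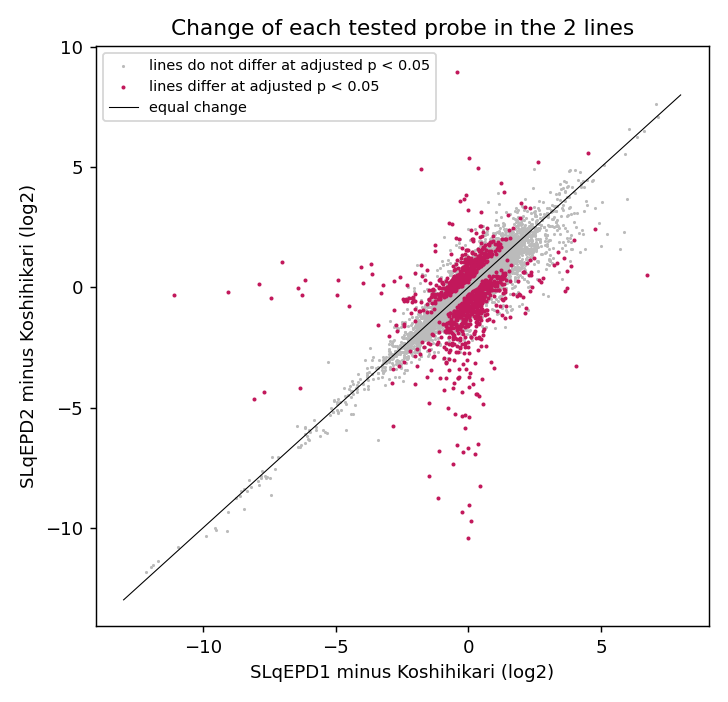
Each dot is 1 of the 32532 tested probes, with its log2 change from Koshihikari in SLqEPD1 (horizontal) and SLqEPD2 (vertical), and the line marks equal change. Most probes lie along that line (r = 0.85), and the 1069 probes at which the lines differ at an adjusted p under 0.05 are coloured.

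The third comparison set SLqEPD1 against SLqEPD2, which asks where the effects of the 2 loci differ. At 1069 probes (3.29%) the lines differed, with 586 higher and 483 lower in SLqEPD1, and 277 and 147 of these differed at least 2-fold. At an unadjusted p under 0.05 there were 4989 probes. SLqEPD1 stood apart from both other groups at 433 probes, 211 higher and 222 lower, and SLqEPD2 at 737 probes, 304 higher and 433 lower. Both counts include the 112 probes at which the lines moved in opposite directions from Koshihikari. With the deposited values the probes standing apart were 650 higher and 143 lower for SLqEPD1 and 201 higher and 913 lower for SLqEPD2. Without SLqEPD2 replicate 1 the lines stood apart at 234 and 404 probes, without SLqEPD1 replicate 3 at 283 and 445, and without SLqEPD1 replicate 2 SLqEPD1 did at 270. The largest difference measured on both sides was at NIAS16130, with the sequence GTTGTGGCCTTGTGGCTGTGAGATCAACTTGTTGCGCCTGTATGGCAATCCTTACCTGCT. It was low in SLqEPD2, at -7.75 ± 0.13 (SD, n = 3), against -0.58 ± 0.09 in SLqEPD1 and -0.83 ± 0.01 in Koshihikari. The lines differed there by 7.16 ± 0.08 (SE, limma, adjusted p = 1.7e-09). NIAS25304, with the sequence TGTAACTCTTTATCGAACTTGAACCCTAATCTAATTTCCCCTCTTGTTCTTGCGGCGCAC, was high in SLqEPD1, at -1.21 ± 0.13 against -7.43 ± 0.18 in SLqEPD2 and -7.94 ± 0.08 in Koshihikari, and the lines differed by 6.22 ± 0.11 (limma, adjusted p = 2.24e-08). NIAS15308, with the sequence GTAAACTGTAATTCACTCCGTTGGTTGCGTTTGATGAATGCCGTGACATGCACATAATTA, was high in SLqEPD2, at 2.27 ± 0.03, and lay at -3.10 ± 0.19 in SLqEPD1 and -3.12 ± 0.37 in Koshihikari (difference between lines -5.37 ± 0.18, limma, adjusted p = 1.16e-06). NIAS05548, with the sequence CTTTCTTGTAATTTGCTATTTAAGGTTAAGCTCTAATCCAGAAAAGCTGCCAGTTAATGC, was low in SLqEPD1, at -7.95 ± 0.22 against -2.74 ± 0.28 in SLqEPD2 and -3.04 ± 0.25 in Koshihikari (difference -5.21 ± 0.18, limma, adjusted p = 1.73e-06). With normexp the differences between the lines were 5.32 at NIAS16130, 4.64 at NIAS25304, -5.28 at NIAS15308 and -3.41 at NIAS05548, and the deposited values gave -4.51 at NIAS05548. Signal was well above background on all SLqEPD1 arrays and no SLqEPD2 array at 61 called probes. The bound reached 601-fold and was at least 2-fold at 54 of them. The reverse held at 24, with a bound of up to 952-fold and of at least 2-fold at 23. Arrays of the lines did not overlap at 21.5% of the probes, against 10% by chance. With the slide as a fixed block 402 probes passed. In that fit SLqEPD2 replicates 1 and 2, alone on slide B, add nothing to the difference between the lines. That difference is therefore 3 SLqEPD1 arrays against SLqEPD2 replicate 3, as in the comparison within slide C, and was 7.26 at NIAS16130. Within slide C the lone SLqEPD2 array is assumed to vary like the SLqEPD1 arrays, which alone supply the spread. In both fits its own deviation cannot be separated from the difference between the lines. Without SLqEPD2 replicate 1 the count was 557, without SLqEPD1 replicate 2 it was 696 and without SLqEPD1 replicate 3 it was 646. With the deposited value table the count was 1842, of which 82.3% were higher in SLqEPD1 against 54.8% here.

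**Figure D3:**
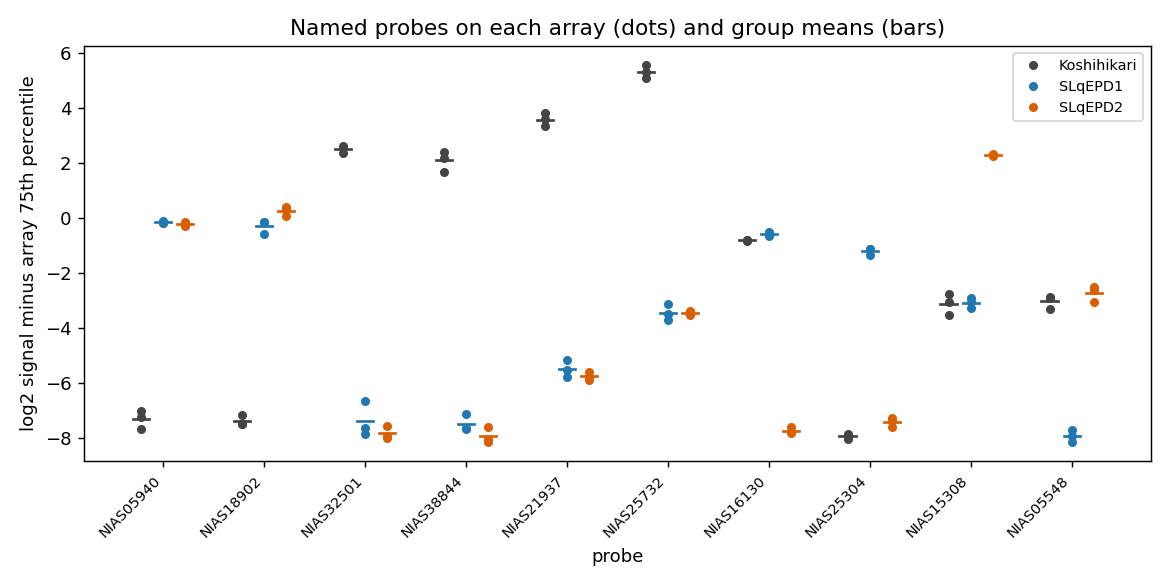
Log2 signal minus the array's 75th percentile (vertical) for the 10 named probes on each of the 9 arrays; dots are arrays and short bars are group means. The first 6 probes differ between Koshihikari and both lines, and at the last 4 a single line stands far from the other groups, as at NIAS16130 with -7.75 in SLqEPD2.

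The position of the called probes was tested in 88 windows of 500 consecutive probe numbers, since a substitution line differs from its background by a chromosome segment. Probes that differed between the lines were enriched in 7 windows, which form 2 runs. The first run, numbers 4501 to 6000, held 186 called probes among 1233 tested (15.1%), and SLqEPD1 was lower at 135 of them and higher at 51. In the second, numbers 14501 to 16500, 321 of 1581 probes (20.3%) were called, with SLqEPD1 higher at 231 and lower at 90. Outside the runs 562 of 29718 probes (1.89%) were called. The runs thus held 47.4% of the calls and 8.65% of the tested probes, and their least enriched window had an adjusted p of 3.89e-06 by Fisher's exact test. Neighbouring probes are not independent, so Fisher's p-values for windows are too small. The highest count in any window after block shuffling was 63. The outer windows of the first run held 45 and 35 calls, so the shuffling does not bear out the extent of that run. SLqEPD1 stood apart from both other groups at 146 probes of the first run and 89 of the second, and SLqEPD2 at 77 and 277. These counts overlap: 37 probes of the first run and 47 of the second, where the lines moved in opposite directions from Koshihikari, count for both lines. NIAS05548 lies in the first run and NIAS16130 and NIAS15308 lie in the second, while NIAS25304 lies in neither. NIAS05940, which was higher in both lines, also lies in the first run, and the lines differed there by 0.08 ± 0.15 (SE, limma, adjusted p = 0.874).

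**Figure D4:**
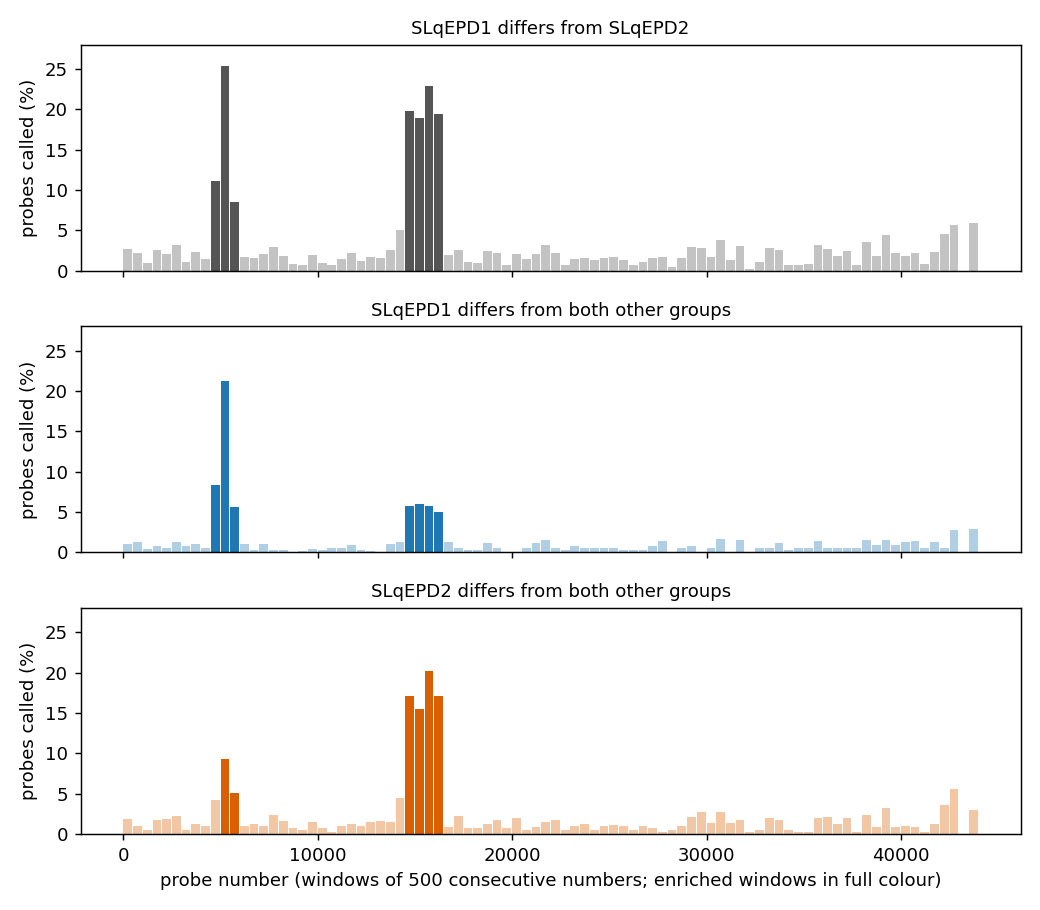
Percent of tested probes called (vertical) in each window of 500 consecutive probe numbers (horizontal), for the difference between the lines and for each line standing apart from both other groups. Full colour marks windows enriched at an adjusted p under 0.05; the highest window of the top panel, at 25.4%, lies in the run from 4501 to 6000.

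Against Koshihikari fewer windows were enriched at this threshold. There 43.3% and 47.6% of all tested probes were called, against 3.29% between the lines, which leaves less room for enrichment. SLqEPD1 calls were enriched in 2 windows, with 223 of 406 probes (54.9%, adjusted p = 6.92e-05 by Fisher's exact test) in numbers 4501 to 5000 and 261 of 418 (62.4%, adjusted p = 1.96e-13) in 5001 to 5500. SLqEPD2 calls were enriched in 1 window, 15501 to 16000, with 259 of 415 probes (62.4%, adjusted p = 6.71e-08). Shuffling blocks of neighbouring probes gave a permutation p of 1e-04 for the fullest window in each of the 3 comparisons, the smallest that 10000 draws can give. Probes changed at least 2-fold in both lines were enriched in 5 windows, and for these the block permutation p was 0.7. The number of enriched windows per comparison with Koshihikari depended on the settings, from 2 to 5 for SLqEPD1 and from 1 to 8 for SLqEPD2.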

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

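The test of which line leads in each run was chosen only after the runs were seen; the test on overlapping probes was fixed before its result.

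The change from Koshihikari differed between SLqEPD1 and SLqEPD2 at 1069 probes, by the direct test of one line against the other, and this difference between groups is what drew attention. Of the 10 splits of these 6 arrays into 3 and 3, 1 gave as many probes, the real one, and the highest of the others gave 0. With 10 splits a share under 0.05 cannot be reached. For SLqEPD1 against Koshihikari the real split gave 14102 probes and for SLqEPD2 15488; in both, 1 of 10 splits gave as many and the highest other gave 0, and these splits are too few for the same reason.

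At 112 probes the lines moved in opposite directions from Koshihikari, with SLqEPD1 higher at 62 and lower at 50. The 2 moves can be very unequal. At NIAS16130, 1 of these probes, the log2 difference from Koshihikari was 0.24 in SLqEPD1 (limma, adjusted p = 0.0425) and -6.92 in SLqEPD2. The sizes over all 112 were not summarized. The direct test between the lines also called all 112, which follows almost by their selection and is no further evidence. Of these probes 84 lie in the runs, 37 in the first and 47 in the second.

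Of the probes that differ between the lines, 47.4% lie in 2 runs of consecutive numbers. Overlapping probes of 1 transcript as the whole cause are argued against: with neighbours that share 12 or more bases merged, 7 windows were enriched, against 7 without merging. A biological hypothesis is that the numbering follows the genome and that each run is the Habataki segment of 1 line. SLqEPD1 led in the first run by 1.9 times and SLqEPD2 led in the second by 3.11 times, where at least 2 times in each had been asked for. A different line led in each run, but the first value falls short, so the hypothesis stays open. The shortfall may come from the way of counting. The 37 and 47 probes of the runs with opposite directions stand in both lines' counts, which lowers both ratios. Ratios without them were not computed. Calls against Koshihikari also differed by line. In the first run's windows they were 48.4% to 62.4% for SLqEPD1 and 45.5% to 53.4% for SLqEPD2. In the second run's windows they were 50.6% to 62.4% for SLqEPD2 and 40.5% to 43.6% for SLqEPD1. Over all tested probes they were 43.3% for SLqEPD1 and 47.6% for SLqEPD2. Positions of the probes in a genome were not used here and would decide whether each run is such a segment.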

How the results depend on the processing

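Counts of lines standing apart, the comparison within slide C and the merging of neighbouring probes were chosen only after seeing the data. All 264 values of named probes under the alternatives kept their direction and their side of the threshold. These probes were picked from the same data for their large changes, so this was nearly fixed in advance. NIAS32501, NIAS38844 and NIAS25304 had no value where detection on every array was required. Sizes did change: with normexp most large changes shrank, such as -5.21 to -3.41 at NIAS05548, 7.16 to 5.32 at NIAS16130 and 7.16 to 5.56 at NIAS05940. Of the 222 counts 184 stayed within 1.5 times. Stricter thresholds lowered the counts of probes by construction, while the enriched windows for the lines against Koshihikari rose from 2 and 1. At 2-fold or more they were 3327 for SLqEPD1 against Koshihikari, 3828 for SLqEPD2, 424 between the lines, 2572 shared, and 122 and 263 for SLqEPD1 and SLqEPD2 standing apart, with 4 and 8 enriched windows for the lines against Koshihikari. At an adjusted p under 0.01 they were 8744, 10216, 500, 7184, 175 and 355, with 4 windows for SLqEPD2 against Koshihikari. The deposited value table gave 1842 probes between the lines, 1516 higher and 326 lower in SLqEPD1, and 793 and 1114 standing apart; its added offset in the SLqEPD1 columns raises dim values there, and the median change over all probes for SLqEPD1 against Koshihikari was 0.11 with it, 0.02 as reported and -0.02 with median scaling. The balance of directions for SLqEPD1 standing apart, 211 higher and 222 lower, turned without Koshihikari replicate 1 (172 and 170), Koshihikari replicate 3 (205 and 182), SLqEPD2 replicate 2 (185 and 159) and SLqEPD1 replicate 3 (144 and 139). With the slide as a fixed block 402 probes differed between the lines, and 148 did within slide C, where the single SLqEPD2 array adds nothing to the estimate of spread; windows numbered 8 and 6 there. Leaving out 1 array gave 557 to 1000 probes between the lines, 234 to 387 for SLqEPD1 apart, 404 to 731 for SLqEPD2 apart and 1 to 3 windows for SLqEPD2 against Koshihikari. The lowest of these probe counts came without SLqEPD2 replicate 1; without SLqEPD1 replicates 2 and 3 the lines differed at 696 and 646 probes, SLqEPD1 stood apart at 270 and 283, and SLqEPD2 at 445 without SLqEPD1 replicate 3. Each such fit has fewer samples. The estimate of array weights stopped before its convergence tolerance was met; its counts stayed within 1.5 times. Enriched windows for SLqEPD1 against Koshihikari were 4 with normexp, 5 with every probe ID on its own and 4 with windows of 250 numbers; for SLqEPD2 they were 3 without a detection filter, 2 with a trended robust variance and 2 with windows of 250 numbers. Between the lines windows of 250 numbers gave 13 and the wider windows gave 4, which follows from their width; for the other window counts the cause was not tested. Same-numbered arrays of different groups deviated with correlations of -0.196 to 0.364, 4 of 9 above 0.1. Arrays with different numbers gave -0.398 to 0.397, 7 of 18 above 0.1. The check thus gave no sign that the numbers pair the samples, but with 3 arrays per group it cannot exclude it. With the replicate block 14646, 16143 and 911 probes passed in the 3 comparisons and SLqEPD2 against Koshihikari had 2 enriched windows. Gene list tests and the test per chromosome were not run. Dim signals limit folds against undetected probes to approximate lower bounds.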

Other observations

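The tests on the slide, on shared segments and on the handling of the Koshihikari group were chosen only after the results were seen; the test on neighbouring probes in and outside the runs was fixed before its result, and the test by direction was added after that one, with its interval added once its ratio was seen.

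Some transcripts were seen in Koshihikari and in neither line, or the reverse. At 63 probes the signal was well above background on all Koshihikari arrays and on no array of either line. Both comparisons were past the threshold there, and 13 of these probes had bounds of at least 32-fold against both lines. The reverse held at 187 probes, of which 2 had bounds of at least 32-fold. The 4 probes with the highest bounds, chosen after their values were seen, have consecutive numbers, 15128 to 15131, and do not share 12 or more bases with each other. NIAS15131 shares 35 bases with the next probe in number order, which is not among the 63, and the reason was not examined. The levels of the 4 probes in Koshihikari were 1.05 ± 0.61, 1.60 ± 0.65, 1.24 ± 0.71 and 1.51 ± 0.61 (log2 relative to the array's 75th percentile, SD, n = 3). Their approximate bounds against both lines were 1085-fold, 1592-fold, 1242-fold and 1494-fold. The 4 probes lie inside the second run, although both lines lack their signal.

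Most probes that differ from Koshihikari differ alike in both lines. A slide effect stays open: within SLqEPD2, the array on slide C differed from those on slide B with an SD over probes of 0.357, which is 0.452 times the SD of 0.790 for the lines against Koshihikari, but this rests on 1 array and sets no limit on an effect of slide A. Habataki segments carried by both lines stay open too: the 5 windows of probe numbers with the highest share of probes changed at least 2-fold in both lines held 3.46% of these probes, which decides nothing, since these windows hold too few tested probes to have held most of them and the probes have no genome positions here. Growth, harvest or RNA handling of the Koshihikari plants, or an effect of slide A alone, cannot be told apart from the cultivar, because 0 slides hold Koshihikari together with a line. A difference that both lines share against this Koshihikari stock stays open and untested.

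In each run the line that stands apart at more probes is mostly the lower one there: SLqEPD1 was lower at 108 and higher at 38 probes of the first run (74.0% lower), against 43.9% lower outside the runs (Fisher's exact test, two-sided, p = 2.89e-08). SLqEPD2 was lower at 205 and higher at 72 probes of the second run (74.0%), against 54.6% outside (Fisher's exact test, two-sided, p = 3.81e-07); neighbouring probes are not independent, so both p-values are too small. The other line stood apart the opposite way. SLqEPD2 was higher at 58 and lower at 19 probes of the first run, and SLqEPD1 higher at 62 and lower at 27 of the second. That is no further evidence, since a probe standing apart must follow the sign of the difference between the lines. In addition, 37 probes of the first run and 47 of the second count for both lines. Single mismatches between probes and Habataki sequence may contribute, and this stays open: among neighbouring probes that share 20 to 55 bases, with at least 1 called between the lines, the median disagreement of the log2 difference was 0.153 in the runs (58 pairs) and 0.0762 outside (57 pairs), a ratio of 2.01 (permutation p = 6e-04, two-sided, 10000 draws), but that test takes in both directions, and in the runs the disagreement where the leading line was lower (45 pairs) was 1 times that where it was higher (13 pairs; 95% bootstrap interval of the ratio 0.432 to 2.93), too wide to decide. A probe can enter more than 1 of these pairs, so that permutation p may be too small as well. Lower transcript levels from the Habataki alleles stay open too. Both probes were called in the same direction at 29 of the 58 pairs in the runs, much as at 31 of the 57 outside. In either place 0 pairs were called in opposite directions.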
